A study of Bos taurus with 9 samples.

How the data were processed

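Gene expression was measured by RNA sequencing in 9 libraries labelled as bovine endometrial epithelial cells, 3 each of untreated control, DPPA3 mRNA and reagent alone. Total RNA was extracted with TRIzol, treated with DNase and made into libraries with the IDT xGen RNA kit, per the labels. The authors deposited a table of raw read counts per gene, keyed by gene symbol. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and edgeR. Their roles and versions, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Whether counting used strand is not stated, so overlapping and antisense genes cannot be told apart. Of 30641 symbols, 24552 (80.1%) matched a RefSeq gene table of the assembly ARS-UCD2.0, which served for gene spans only.

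The counts were tested as deposited. Genes with low counts were removed with filterByExpr, which left 14874. Libraries were scaled with TMM factors, and the 3 groups were fitted together with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common biological coefficient of variation was 0.26. Standard errors are the log2 fold change divided by the square root of the F statistic, and CPM values use the TMM-scaled library sizes. The floor for a count of 0 was 3 counts per library, between 0.226 and 0.747 CPM. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 13.7, so none was treated as a duplicate.

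The 27 gene lists, the comparisons and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over 25 lists). The text names DPPA3; up to 8 called genes with the largest rise and 8 with the largest fall that had a symbol, a mean of at least 5 CPM and no overlap between groups; and up to 4 members of each list with the smallest p. IFITM1 against reagent alone and other genes outside this rule were named after their values were seen.

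The replicate numbers recur in each group. Deviations from the group means correlated between equal numbers of the DPPA3 mRNA and untreated control groups at 0.34, 0.32 and 0.12. All lay over the limit of 0.1, so these numbers were taken to pair the samples from the data, not from the labels.

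The alternatives were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, only the 6 libraries compared, a replicate block, DPPA3 left out of library sizes, each library left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were limma voom with quality weights, the block without untreated control replicate 1, DPPA3 mRNA replicate 2 and reagent alone replicate 3 left out together, and all libraries thinned to the smallest total. The scripts were tested on simulated data with 200 changed genes per comparison. For DPPA3 mRNA against reagent alone, 7 of 14632 unchanged genes were called, against 15 of 14631 for DPPA3 mRNA against untreated control and 6 of 14632 for reagent alone against untreated control.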

Results

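RNA was sequenced from cells labelled as bovine endometrial epithelial cells in 9 libraries, 3 in each of 3 groups. Cells of the untreated control group received neither reagent nor RNA. Cells of the DPPA3 mRNA group were given 500 ng of DPPA3 mRNA made by in vitro transcription, with the transfection reagent jetMESSENGER, 24 hours after seeding. Cells of the reagent alone group received jetMESSENGER without RNA at the same time. The total counts were 7258348, 9028012 and 10130619 in untreated control replicates 1 to 3, 3890134, 10985010 and 12092771 in reagent alone replicates 1 to 3, and 13258036, 11070923 and 11566588 in DPPA3 mRNA replicates 1 to 3. The table listed 30641 genes, of which 14874 had enough counts to be tested. Nothing in the labels says that the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

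The transfected transcript was examined first, since it checks the labels. DPPA3 had 126334, 213790 and 213192 counts in DPPA3 mRNA replicates 1, 2 and 3, which was 0.953%, 1.93% and 1.84% of all counts. The exact (Clopper-Pearson) 95% intervals were 0.948% to 0.958%, 1.92% to 1.94% and 1.84% to 1.85%, and cover counting error only. Its mean was 15645 ± 5334 CPM (normalised read count; SD, n = 3). The untreated control libraries held 0, 2 and 1 counts of DPPA3, and each reagent alone library held 0. Set against a floor of 3 counts in each reagent alone library, DPPA3 was at least 37462-fold higher in the transfected cells. Against the 3 counts pooled over the untreated controls the ratio was 133859, with a 95% counting interval of 45804 to 649095. DPPA3 passed the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in both comparisons (adjusted p 1.42e-08 against reagent alone and 1.56e-08 against untreated control). The counts do not tell transfected RNA from a transcript made by the cells.

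**Figure D1:**
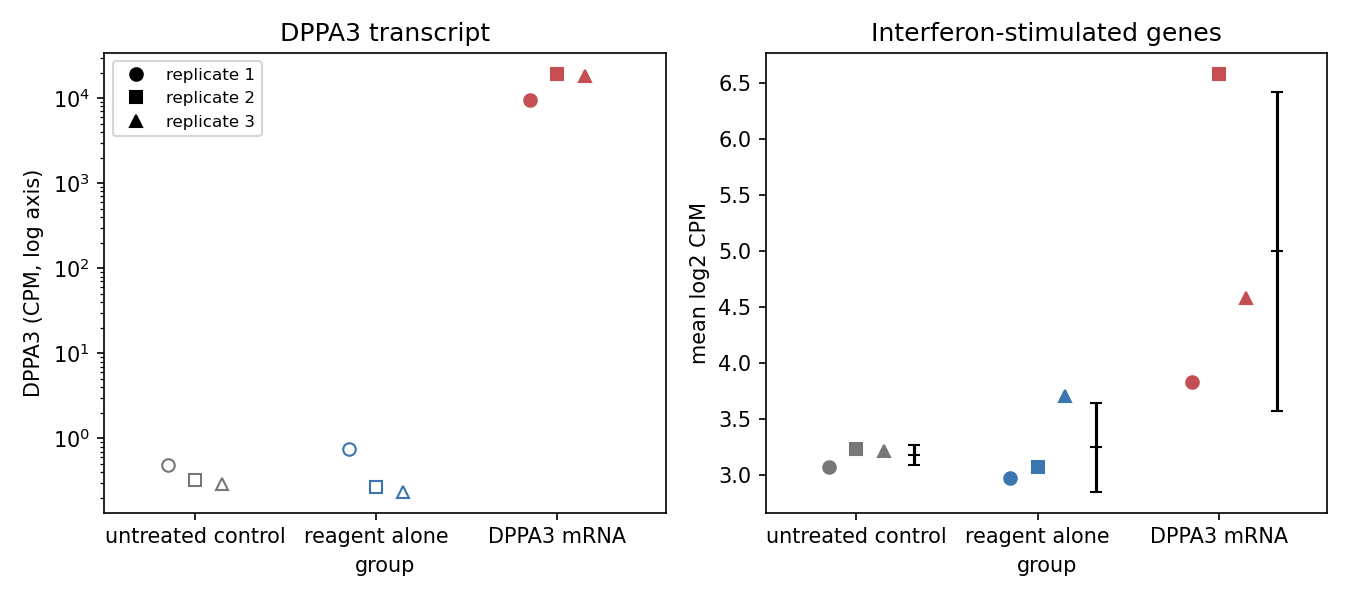
DPPA3 in CPM on a log axis (left) and the mean log2 CPM of the interferon-stimulated list (right) in each library of the 3 groups; open symbols are libraries with 3 counts or fewer, drawn at the floor of 3 counts, and the black bars on the right are the mean and SD. DPPA3 lay at 9526 CPM or more in the transfected libraries, and the list was highest in DPPA3 mRNA replicate 2, at 6.58.

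The comparison of DPPA3 mRNA with reagent alone asked what the mRNA changed in cells that all received the reagent. No group received another mRNA, so the comparison does not separate the DPPA3 sequence from the presence of an in vitro made mRNA. DPPA3 was the 1 gene called by edgeR's quasi-likelihood test, with 0 genes called lower, and 248 of the 14874 genes had an unadjusted p under 0.05, where chance gives 743.7. That count was 495 with only the 2 groups compared and 895 with limma voom, and ranged from 208 to 993 over the alternatives. The next smallest adjusted p was 0.312, for IFITM1, whose level was 28.9 ± 12.5 CPM with DPPA3 mRNA and 6.32 ± 2.42 CPM with reagent alone (SD, n = 3; log2 fold change 2.19, SE 0.37). DESeq2 called 10 genes. They were DPPA3, IFITM1, ENO4, DHX58, OAS1X, TNFSF10, IFI6 and genes with only a LOC number. ENO4 belonged to no fixed list (log2 fold change 6.35, DESeq2 adjusted p 0.0027). In simulated data for this comparison, 36.8% of genes changed 2-fold, 74.6% of those changed 4-fold and 87.7% of those changed 8-fold were called. The simulated libraries of a group shared the same mean for each gene, with no differences between replicate numbers or in the size of a response. The shares may be lower in the real data. RSAD2 had a log2 fold change of 6.84 and was not called (edgeR adjusted p 0.47).

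Of 27 gene lists fixed before the data were examined, 25 had at least 5 tested members, and 2 passed the threshold of the camera test with a preset correlation of 0.01. The 45 tested members of the list of interferon-stimulated genes had a median log2 fold change of 1.98, and 45 of them were higher on average with DPPA3 mRNA than with reagent alone (adjusted p 6.6e-63). This call was lost with a correlation estimated from the data, 0.80 for this list (adjusted p 0.23), and with fry (0.88). Over all genes tested 0 of these members were called, and 36 were called higher when adjusted over the list alone. In 18 members every transfected library lay above every reagent alone library, where chance gives 5% in this direction for each gene. The members vary together (estimated correlation 0.80), so they are not 18 separate observations.

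The rise differed in size between the transfected libraries. IFI6 measured 21.3, 461 and 88.8 CPM in DPPA3 mRNA replicates 1, 2 and 3, against 2.72, 5.84 and 15.3 CPM in reagent alone replicates 1, 2 and 3 (log2 fold change 4.47, SE 0.88; edgeR adjusted p 0.47 over all genes). MX1 measured 27.9, 669 and 116 CPM in the transfected libraries and 15.3 ± 10.2 CPM (SD, n = 3) with reagent alone. RSAD2 measured 8.82, 225 and 7.21 CPM, against 0.55 ± 0.52 CPM. OAS1X measured 35.2 ± 43.8 CPM against 0.62 ± 0.51 CPM, and its reads may be shared with near-identical copies such as OAS1Y, as may those of IFITM1 with its family. The mean log2 CPM of the list was 3.83, 6.58 and 4.58 in DPPA3 mRNA replicates 1 to 3, 2.97, 3.07 and 3.70 in the reagent alone libraries and 3.08, 3.24 and 3.22 in the untreated controls. A two-sided exact permutation test of these means gave p = 0.1 for DPPA3 mRNA against reagent alone, the smallest that 3 against 3 allows. Without DPPA3 mRNA replicate 2 the list's median fell from 1.98 to 0.65 and the members called over the list alone from 36 to 11. Without DPPA3 mRNA replicate 1 the median was 2.56 and 42 members were called over the list alone. Over all genes 20 were then called, among them IFI6 and OAS1X (edgeR adjusted p 0.0096 for both), MX1 (0.0099) and RSAD2 (0.025).

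**Figure D2:**
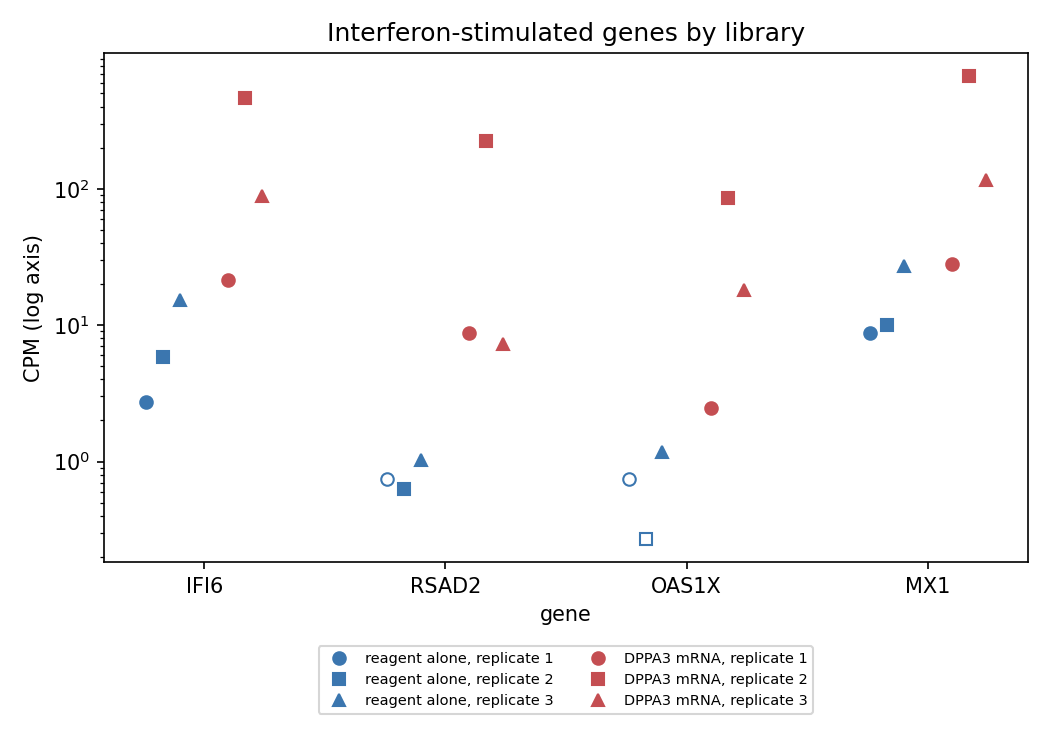
CPM on a log axis of IFI6, RSAD2, OAS1X and MX1 in each library of the reagent alone and DPPA3 mRNA groups; open symbols are libraries at or under the floor of 3 counts, drawn at that floor. DPPA3 mRNA replicate 2 held the highest value of each gene.

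The list of antigen processing and presentation genes had a median log2 fold change of 0.34 over 22 members (camera adjusted p 6.7e-06), and 0 members were called, over all genes or over the list alone. That call was lost with the estimated correlation (adjusted p 0.23) and with fry (0.81), and the adjusted p ranged from 9.4e-08 to 0.81 over the alternatives. Without DPPA3 mRNA replicate 2 its median was 0.19 and its adjusted p 0.069. The list of NF-kB targets, cytokines and chemokines did not pass (adjusted p 0.64), and TNFSF10 was its 1 member called over the list alone. TNFSF10 measured 0.75, 24.5 and 4.92 CPM in DPPA3 mRNA replicates 1 to 3, against 0.11 ± 0.10 CPM with reagent alone (SD, n = 3), which lies under the floor. Its fitted log2 fold change over reagent alone, which depends on the prior count and is no bound, was 6.03 (SE 1.23, edgeR adjusted p 0.50 over all genes). It fell to 4.24 without DPPA3 mRNA replicate 2. In untreated control replicates 1 to 3 TNFSF10 measured 1.45, 0.32 and 0.68 CPM, so DPPA3 mRNA replicate 1 lay within their range. Against untreated control its log2 fold change was 3.67 (edgeR adjusted p 0.85), and 1.83 without DPPA3 mRNA replicate 2.

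The series is titled as a study of pregnancy-related genes, and a list of pregnancy and receptivity genes of the ruminant endometrium was tested for that reason. Its 48 tested members had a median log2 fold change of -0.06 against reagent alone (camera adjusted p 0.56) and -0.12 against untreated control (adjusted p 0.18). In both comparisons 0 members were called, over all genes or over the list alone. The first median changed sign without reagent alone replicate 2, to 0.03. Without DPPA3 mRNA replicate 2 the list passed as lower against untreated control (median -0.10, adjusted p 0.031, with 0.031 to 0.80 over the alternatives). HOXA10 had the smallest p of the list in both, at 6.84 ± 0.50 CPM with DPPA3 mRNA, 10.7 ± 3.50 CPM with reagent alone and 10.6 ± 1.91 CPM in untreated cells (SD, n = 3).

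The comparison of DPPA3 mRNA with untreated control measured reagent and mRNA together. DPPA3 and IFITM1 were called higher and 0 genes lower, and 582 genes had an unadjusted p under 0.05, where chance gives 743.7. That count was 1391 with the replicate block, 201 without DPPA3 mRNA replicate 2, and 378 and 2874 without untreated control replicates 1 and 2. IFITM1 was at 28.9 ± 12.5 CPM against 4.19 ± 0.91 CPM (SD, n = 3; log2 fold change 2.77, SE 0.38; edgeR adjusted p 0.037). That call was lost on leaving out any 1 of the 6 libraries except DPPA3 mRNA replicate 1, and the adjusted p then ranged from 0.076 to 0.26. It was also lost with only the 2 groups compared (adjusted p 0.085) and with DPPA3 left out of library sizes (0.075). The log2 fold change stayed at 2.77 in both. The second setting also took DPPA3, the 1 gene with a smaller p, out of the test. That by itself raises the adjusted p of IFITM1, so the loss is not read as an effect of library sizes. The call thus rested on counting the transfected gene among the genes tested. Over all alternatives the adjusted p ranged from 3.5e-11 to 0.26. DESeq2 called 12 genes. With the replicate number as a block, since the numbers pair the samples of these groups, 7 genes were called, 6 higher and 1 lower, and IFITM1 had an adjusted p of 0.0055.

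Against untreated control 3 lists passed the camera test. The share of ribosomal RNA was also lower here, at 1.005% to 1.10% against 1.14% to 1.56% of counts. Interferon-stimulated genes had a median log2 fold change of 2.14 (adjusted p 7.4e-41), with 0 of 45 members called over all genes and 36 adjusted over the list alone. This call was lost with the estimated correlation (adjusted p 0.53) and with fry (0.56). With the replicate number as a block the median of this list was 1.72 (camera adjusted p 1.1e-42). That call was also lost with the estimated correlation (adjusted p 0.735) and with fry (0.364). Antigen processing and presentation genes had a median of 0.38 (adjusted p 5.2e-04) and ribosomal proteins of 0.10 (adjusted p 0.023, and 0.058 with the replicate block). With the estimated correlation or fry 0 lists passed, with adjusted p of 0.53 and 0.56 for antigen processing and 0.91 and 0.76 for ribosomal proteins. Without DPPA3 mRNA replicate 2 the median of the interferon-stimulated list was 0.75. The antigen processing median ranged from 0.21 without DPPA3 mRNA replicate 2 to 0.51 without DPPA3 mRNA replicate 3. For ribosomal proteins it ranged from 0.046 without DPPA3 mRNA replicate 1 to 0.19 without DPPA3 mRNA replicate 2. Without untreated control replicate 2 the antigen processing list had an adjusted p of 0.060, and the ribosomal list lost its call without DPPA3 mRNA replicate 1 (adjusted p 0.46), DPPA3 mRNA replicate 3 (0.14) or untreated control replicate 3 (0.057).

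The comparison of reagent alone with untreated control gave the background of the reagent. By edgeR 0 genes were called, and 0 lists passed. DESeq2 called 2 genes lower, LOC112442278 (adjusted p 0.0080), at 63.7 ± 3.995 CPM against 165 ± 82.2 CPM, and MIR2887-1 (0.013), at 18.7 ± 3.16 CPM against 57.6 ± 32.7 CPM (SD, n = 3). Ribosomal RNA took 1.14% to 1.56% of the counts in the untreated controls, 0.93% to 0.99% with reagent alone and 1.005% to 1.10% with DPPA3 mRNA, so its share moves with both comparisons against untreated control. An unadjusted p under 0.05 was found for 1516 genes, where chance gives 743.7, and for 608 and 4165 without untreated control replicates 1 and 2, and 955 and 814 without reagent alone replicates 1 and 2. Interferon-stimulated genes had a median log2 fold change of 0.11 (camera adjusted p 0.93). The 2 lists with the smallest p were immediate early genes (median -0.27) and the unfolded protein response of the endoplasmic reticulum (median 0.11), each with an adjusted p of 0.31. DNAJB11 had the smallest p of the latter list, at 48.4 ± 3.54 CPM with reagent alone and 31.3 ± 4.16 CPM in untreated cells (SD, n = 3; log2 fold change 0.62, SE 0.17; edgeR adjusted p 0.47). Without untreated control replicate 1 the median of the immediate early list was 0.04. The list passed as lower without untreated control replicate 3 (median -0.34, adjusted p 0.034) and without reagent alone replicate 1 (median -0.36, adjusted p 0.046), and its adjusted p ranged up to 0.96 over the alternatives.

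**Figure D3:**
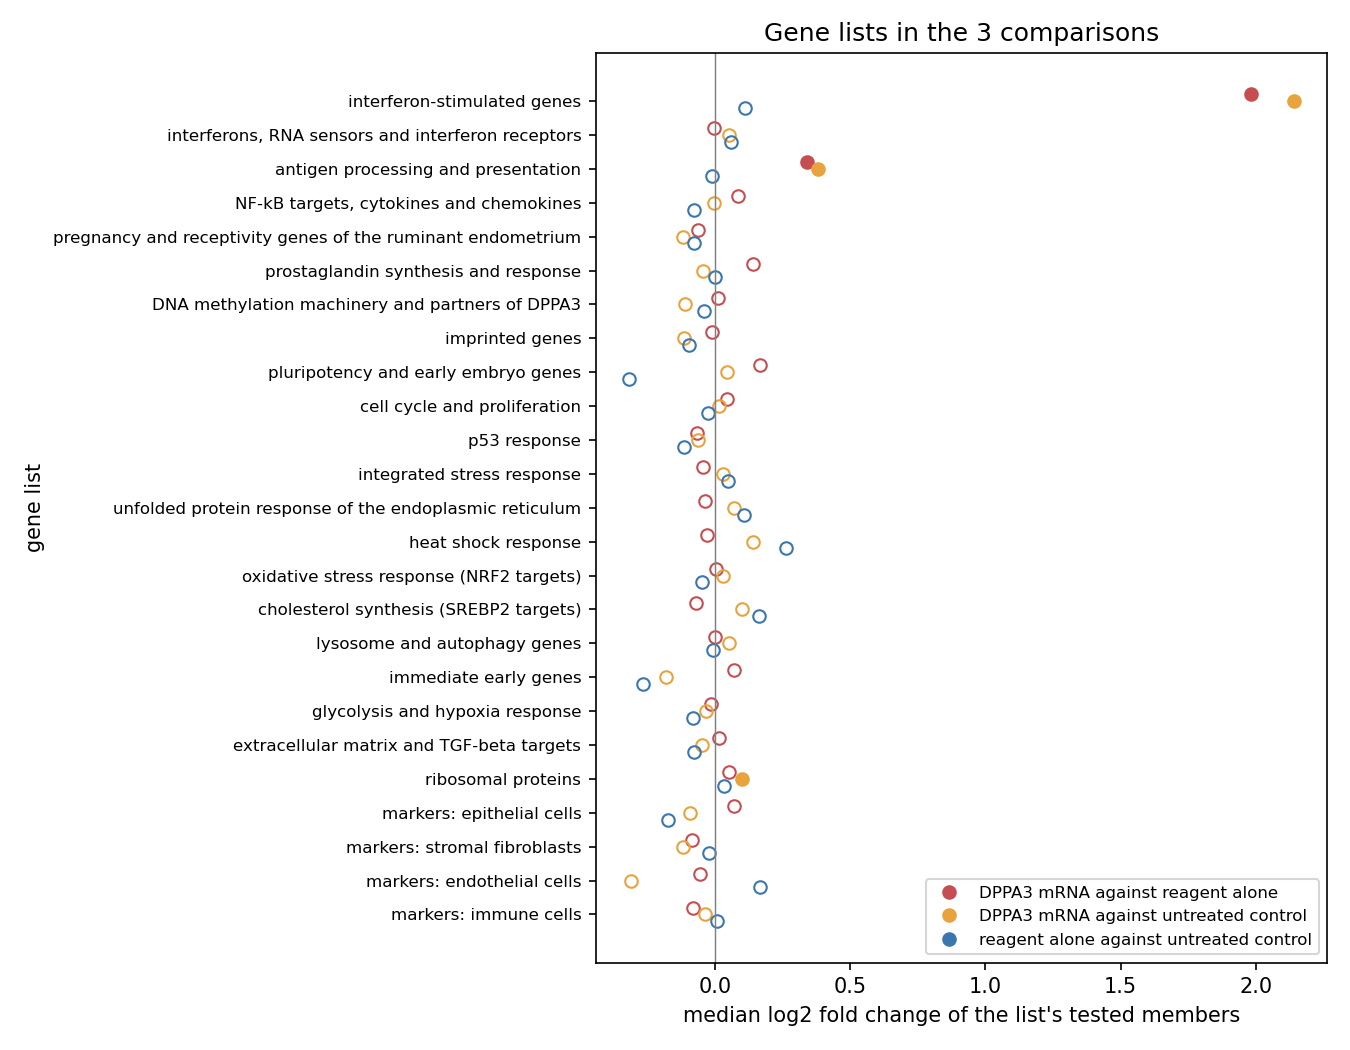
Median log2 fold change of the tested members of each of 25 gene lists in the 3 comparisons; filled symbols passed the camera test with the preset correlation. Interferon-stimulated genes stood at 1.98 and 2.14 in the comparisons with DPPA3 mRNA and at 0.11 with reagent alone.

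The remaining tested lists did not pass in any comparison. They were interferons, RNA sensors and interferon receptors; prostaglandin synthesis; DNA methylation machinery and partners of DPPA3; imprinted genes; pluripotency genes; cell cycle; p53, integrated stress, heat shock and oxidative stress responses; cholesterol synthesis; lysosome and autophagy; glycolysis and hypoxia; extracellular matrix; and markers of epithelial, stromal, endothelial and immune cells. The smallest adjusted p of a list that did not pass was 0.48 against reagent alone, 0.18 for DPPA3 mRNA against untreated control and 0.31 for reagent alone. The germ line list had 1 tested member, too few for the test. Of the 13 members of the mitochondrial list, 0 were found in the count table by symbol. That list was fixed as a sign of RNA quality, so this check could not be made. Of the 25 fixed members of the list of interferons, RNA sensors and interferon receptors, 16 were tested. The interferons IFNT2 and IFNK had 19 and 34 counts over all libraries and were not tested. IFNE measured 2.08 ± 0.44 CPM with DPPA3 mRNA and 1.63 ± 0.33 CPM with reagent alone (SD, n = 3). The result of this list therefore says little about interferon transcripts. The RNA sensors DDX58, IFIH1 and DHX58 belonged to the interferon-stimulated list instead. DESeq2 called DHX58 higher with DPPA3 mRNA than with reagent alone (log2 fold change 2.35, adjusted p 0.0073).

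Both comparisons with the untreated control share its 3 libraries. Across 14873 genes without DPPA3, which are not independent replicates, their log2 fold changes had a correlation of 0.64 and a covariance of 0.16. Simulated unchanged groups that share simulated controls, with the same dispersion in every library, gave 0.51 ± 0.014 and 0.097 ± 0.0040 (mean and SD of 20 simulations), so the covariance exceeded the simulated one by 0.063. Part of the excess may come from the shared controls where their spread is wider than simulated, and they are too few to be split. The simulated libraries also held no differences between replicate numbers, so the excess over groups with such differences was not measured.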

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

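The voom fit, the fits without untreated control replicate 1 together with the block, the fit without DPPA3 mRNA replicate 2 and reagent alone replicate 3, and the thinning were chosen after seeing the data. DPPA3 stayed called under every alternative that tested it, with a log2 fold change over untreated control of 16.53 to 17.71 when single libraries were left out. For DPPA3 mRNA against reagent alone, against untreated control and for reagent alone against untreated control, the genes called were 66, 69 and 18 with no filter, 10, 12 and 2 with DESeq2, and 19, 33 and 6 with the block and without untreated control replicate 1; the cause was not tested. Leaving DPPA3 out of library sizes also removed it from the test, and the first 2 counts became 0 and 0. Leaving out single libraries gave 1 to 20, 1 to 26 and 0 to 1 genes, and the highest of the first 2 came without DPPA3 mRNA replicate 1. The voom fit called 4 genes against untreated control and 2 for reagent alone. Without DPPA3 mRNA replicate 2 and reagent alone replicate 3, 2 genes and 5 lists were called. With the replicate block 2 genes were called against reagent alone, DPPA3 and IFITM1 (log2 fold change 2.20, adjusted p 0.039, with 1.3e-07 to 0.99998 over the alternatives), 7 for DPPA3 mRNA against untreated control and 0 for reagent alone. Correlations between equal numbers were 0.14, 0.12 and 0.086 for DPPA3 mRNA with reagent alone, and 0.15, 0.14 and 0.093 for reagent alone with untreated control, not all over the limit of 0.1, so the block stayed an alternative there. Every sample correlated best with its own number, a hint from the data and not the design. Lists past the threshold fell to 0 with the estimated correlation and with fry in both comparisons of DPPA3 mRNA. They ranged from 2 to 3, 2 to 4 and 0 to 1 when single libraries were left out, and 1 passed for reagent alone with the block and without untreated control replicate 1. The ribosomal list was the 1 list whose call the block changed among those named. The block lowered the median of the interferon-stimulated list from 1.98 to 1.60 against reagent alone. For DPPA3 mRNA against untreated control it lowered that median from 2.14 to 1.72. The correlation of the comparisons was 0.65 with the block, 0.66 with the block and without untreated control replicate 1, 0.55 with DESeq2 and 0.51 to 0.78 without single libraries. The pregnancy list's median against reagent alone became 0.00094 with no filter, and ranged from -0.064 to 0.028 when single libraries were left out, the latter without reagent alone replicate 2. For reagent alone against untreated control such ranges were -0.15 to 0.032 for that list and -0.43 to 0.037 for immediate early genes, the latter of each without untreated control replicate 1, and -0.00076 (without reagent alone replicate 3) to 0.29 for interferon-stimulated genes. None of these 5 passed the threshold under either setting. Of 367 values of named genes and lists under alternatives, 304 kept direction and side of the threshold, 24 lost a call, 34 gained one and 5 changed sign. Among lists past no threshold, 164 of 865 medians changed sign, so no direction is read from them. Reagent alone replicate 1, with 3890134 counts, had the highest floor of its group, at 0.747 CPM, against 0.269 and 0.236 CPM in replicates 2 and 3. The bound of 37462-fold for DPPA3 uses the mean of these floors, 0.418 CPM.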

Other observations

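The tests of immune cells, carried-over RNA, gene span, the most abundant gene, the sequence of the mRNA and the replicate numbers were chosen after the patterns, or values close to those they measure, had been seen. The thinning was added after the data were seen, but before its own result. The other splits were specified before their results were seen.

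Interferon-stimulated genes were higher with DPPA3 mRNA than with reagent alone, and the transfected libraries were deeper on average. After all libraries were thinned to the total of the shallowest, the median log2 fold change was 1.52 over the 41 members still tested, against 1.98 over 45 at full depth, and 10 further thinnings gave 1.43 to 1.71, which argues against depth as the cause. The summed CPM of the 20 immune cell markers was 30.2 ± 3.79 with DPPA3 mRNA and 31.0 ± 5.05 with reagent alone (SD, n = 3), a ratio of 0.975 with an SE of 0.12, which argues against added immune cells. A response to introduced RNA may account for the rise, but 0 groups received an mRNA of another sequence, so it cannot be told apart from a response to the DPPA3 sequence itself.

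Reagent alone replicate 3 held the highest level of 33 of the 45 interferon-stimulated genes within its group, where chance gives 15 for independent genes. These genes vary together (estimated correlation 0.80), so the 2 counts do not measure how unlikely the rise is. To bring that rise, RNA of transfected cells would have to make up a median of 6.53% of the library, and would carry 12973 counts of DPPA3. That library held 0 counts of DPPA3, which argues against RNA of transfected cells carried over. No biological explanation was tested.

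Untreated control replicate 1 stood apart from the other libraries. Of 14874 genes, 3244 lay over 1 log2 unit from the mean of the others, against 516 to 1426 in the other libraries. Removing the trend on gene span left 2746 of 2912 genes with a known span, which argues against gene span as the whole cause. Gene span is not transcript length, which was not tested, so an effect of transcript length or RNA quality stays open. LOC112442408 took 11.0% of its counts and 3.05% to 4.36% of the others, and 3242 genes remained without that gene. No biological explanation was tested, and the cause stays open.

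Genes differed between replicate numbers across all groups. With the number as a term, 219 genes were called by edgeR, and 1 of 36 relabelings of the numbers within groups, the real one, gave as many. The highest of the others was 90. A share of 1 in 36 is the smallest this test allows. The test was also chosen after the pattern, or values close to it, had been seen, so chance is not excluded. ACSL6 measured 16.8, 16.4 and 13.2 CPM in replicate 1 of the untreated control, DPPA3 mRNA and reagent alone groups, and between 62.2 and 93.5 CPM in the other 6 libraries. Equal numbers may share a cell source or a day, which the labels do not state.

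Other splits of 6 libraries make 10 groupings, too few for a share under 0.05. For genes called, 1 of the 10 reached the real 1 gene against reagent alone (highest other 0), 1 reached the real 2 genes for DPPA3 mRNA against untreated control (highest other 0), and 10 reached the real 0 for reagent alone (highest other 0). For lists, 9 of the 10 reached the real 2 against reagent alone (highest other 8), 5 reached the real 3 for DPPA3 mRNA against untreated control (highest other 8), and 10 reached the real 0 for reagent alone (highest other 10). Splits with each replicate number once per side gave 3, 2 and 1 lists against reagent alone and 2, 3 and 1 for DPPA3 mRNA against untreated control, so the shares may also hold differences between replicate numbers.

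LOC100847765, singled out after its values were seen, measured 165 ± 10.8 CPM in untreated cells, 28.4 ± 36.0 CPM with reagent alone and 16.96 ± 9.62 CPM with DPPA3 mRNA (SD, n = 3). Against untreated control edgeR did not call it (adjusted p 0.47 for reagent alone and 0.38 for DPPA3 mRNA). The voom fit and the fit with no filter called it in both comparisons. So did the block without untreated control replicate 1. ENO4, also singled out after its values were seen, measured 340 and 1355 CPM in DPPA3 mRNA replicates 1 and 3, and 6.14 CPM in replicate 2. It measured 8.71 ± 2.67 CPM in untreated cells and 6.92 ± 1.65 CPM with reagent alone (SD, n = 3). DESeq2 called it higher with DPPA3 mRNA than with either (adjusted p 0.0027 and 0.0042 against reagent alone and untreated control). By edgeR it was not called (0.47 and 0.32), except without DPPA3 mRNA replicate 2 and with no filter. In untreated cells COL1A1 measured 13115 ± 5031 CPM, COL3A1 7930 ± 2024 CPM, FN1 23277 ± 5454 CPM, KRT8 4451 ± 493 CPM and EPCAM 0.66 ± 0.12 CPM (SD, n = 3), also looked up after the data were seen. KRT18 measured 1979 ± 540 CPM, KRT19 2791 ± 106 CPM and CDH1 49.5 ± 4.09 CPM in the same libraries. COL1A2 measured 14183 ± 1518 CPM and VIM 1530 ± 188 CPM there. No cell type is read from these genes.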
